A study of Homo sapiens with 6 samples.

How the data were processed

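Expression was measured in HCT116 cells infected for 48 h with a lentivirus carrying a scrambled shRNA or an shRNA against ERRα and then selected with puromycin for 48 h, per the labels' protocols; the medium held 10% serum. Each group has 3 arrays that the labels call biological replicates. Nothing says whether they came from separate infections, so p-values measure only the spread between these samples, which may be partly technical. Groups and replicate numbers were taken from the sample titles.

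The deposited value table holds 1 value per probe set and array in log2 units, summarised and normalised by the authors with RMA, per the submitters' processing notes; the software version, the annotation and the genome build are not given in the sources used here. The decimal marks of this table were lost on deposition, so that each value is a string of digits. Strings of 7 digits were read as values of 10 or more and other strings as 1 digit before the mark, except that 90472 values (5.86%) could be read either way. These took the reading nearer to the unambiguous values of the same probe set. For 1281 probe sets the reading stayed undecided, because the distances of both readings from those values differed by less than 4 log2 units; 12 of them were settled by the deposited fold change and 1269 were left out, which leaves 256161 probe sets. A further 159 probe sets with only ambiguous values were read as low. The reading was checked against the deposited comparison: it gave all 2122 deposited fold changes within 0.001 log2 units and all 2122 deposited p-values within 1%.

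The authors' deposited table of the comparison gives, per the file headers, a fold change, as the ratio of shERRα over shscrambled, and an unadjusted p-value of a t-test for each of 2122 probe sets. All have a p-value under 0.01 and at least a 2-fold change in the deposited values. The same rule applied to the value table selected these 2122 probe sets and no others. All value columns matched a sample.

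Gene names are paired with probe sets in the authors' deposited table alone. Of the 2122 probe sets, 1948 were named through their accession in the RefSeq gene table of assembly GRCh38.p14, 103 by symbol, 27 by an older symbol and 11 by the name the table gives, and 33 stayed unnamed. No coordinates are given because the build of the array annotation is not known. Of the listed probe sets, 42 share identical values with another listed one; these were counted once in the numbers of distinct probe sets per gene.

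The gene-level fit, the camera and fry gene list tests and the counts adjusted over the list alone, which were planned before the data were examined, need names for all probe sets and were not run. In their place limma (version 3.58.1, R 4.3.3) was run with lmFit and eBayes on each probe set, with Benjamini-Hochberg adjustment and a threshold of 0.05, and gene lists were described by their members among the listed genes. For 3 of the 31 lists, those with at least 5 listed members apart from ESRRA, Fisher's exact test compared their directions with those of the other listed genes (scipy 1.17.1). ESRRA, as the target of the shRNA, and genes listed in both directions were left out of that test. The lists and their members were fixed beforehand; the test was chosen after the values were seen.

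Runs of consecutive probe set identifiers served as a stand-in for genes. A missing identifier ends a run. Of 28974 runs, 19186 had at least 3 probe sets, and 19182 could be tested. Of the 318 runs with at least 2 listed probe sets, 317 carried 1 gene name, and 1437 of 1458 symbols lay in 1 run. An unnamed probe set of a run is not known to belong to the gene. The run was summarised per array by its median. The minimum of 3 was chosen after counts for minimums of 1, 3 and 5 had been seen.

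The rule for named genes was ESRRA first, then the genes past the adjusted threshold with the largest changes. With fewer than 5 passing in a direction, it takes the 5 with the smallest p in that direction, and from each list the member with the smallest p. Genes without a characterised product were passed over. Other members of the lists are named as the basis of counts; some members that are counted are not reported here by name. Genes with at least 5 distinct listed probe sets, and VIM, were added after their values were seen. Levels of a gene are medians over its listed probe sets per array, given as mean ± SD over the arrays of a group.

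The code was tested on simulated arrays with 200 changed probe sets or runs. The fitted medians were 0.97 and 2.06 log2 units for probe sets made to change by 1 and 2. Run medians recovered 19.0% and 89.0% of these sizes with 0 unchanged runs called, and with array weights 47.0% and 100% with 7 unchanged runs called.

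The alternatives were a block for the replicate number, leaving out each array, the mean and the brighter probe sets of a run, filters on dim probe sets at percentiles 25 and 50, quantile normalisation, centring on array medians, a trended robust variance, array weights, an equal-variance test in place of limma, and a 1.5-fold threshold. Added after the values were seen were the probe sets and runs as units of testing, runs of other lengths, the rule of the deposited comparison recomputed under each setting, the inclusion of undecided probe sets, the median of probe set changes as a gene's summary, the exclusion of ESRRA from the list tests and genes with at least 2 listed probe sets for the list tests. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.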

Results

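HCT116 cells, an established human colon carcinoma line, were infected with a lentivirus carrying either a short hairpin RNA (shRNA) against ERRα or a scrambled shRNA. Total RNA of 3 biological replicates of each group was hybridised to Affymetrix whole-transcript arrays. ERRα, encoded by ESRRA, is an orphan nuclear receptor known for activating genes of mitochondrial energy metabolism. The value table held log2 expression of 257430 probe sets on the 6 arrays, many probe sets per gene, and 256161 of them were used. Array medians lay between 4.28 and 4.43 log2 units. The number of arrays limits the precision of every value. shERRα replicate 1 stood apart: its correlation across probe sets with each of the other 5 arrays was 0.867 to 0.877, against 0.933 to 0.947 for the 10 pairs among those arrays.

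The only comparison of the design, shERRα against shscrambled, asks which transcripts differ when ERRα is depleted in colon cancer cells. It cannot tell loss of ERRα apart from other effects of the shRNA. ESRRA itself was lower in every shERRα array than in any shscrambled array. The median of its 2 named probe sets was 5.08 ± 0.21 log2 units (SD, n = 3) with the scrambled shRNA and 2.38 ± 0.20 (SD, n = 3) with the shRNA against ERRα, 6.52-fold lower. Probe set 7940995 was at 11.7% of the control level (log2 change -3.10, SE 0.25) and probe set 7940992 at 20.2% (log2 change -2.31, SE 0.34). Levels in shERRα were near background (the 25th percentile of probe set means was 2.41), so the remaining shares and the fold are not exact. Both had an adjusted p of 0.474 in limma over all probe sets. For each, the exact two-sided permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow. Both carry a name only because the authors' comparison lists them for their difference on these same arrays. Their separation and fold are therefore selected. The run of 6 consecutive probe set identifiers that holds both had a median log2 change of -1.84 (SE 0.33). The other 4 probe sets of that run had a median of -0.31, with 2 lower and 2 higher. The pseudogenes ESRRAP1 and ESRRAP2 resemble ESRRA, so cross-hybridisation cannot be excluded for these probe sets.

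The authors' deposited table lists 2122 probe sets at an unadjusted p under 0.01 and at least a 2-fold difference, of which 695 were higher and 1427 lower in shERRα. Under the same rule, leaving out each array in turn gave 513 to 906 higher and 775 to 1705 lower. The number lower was 775 without shscrambled replicate 2, 909 without shscrambled replicate 1 and 1705 without shERRα replicate 2. Part of a fall can come from the smaller number of arrays. The listed probe sets carry 1458 gene symbols: 500 genes were listed higher, 929 lower and 29 in both directions. Gene names were paired only with these probe sets, so each gene below was selected for its difference on these same arrays. Its listing is not independent evidence of its direction, and its fold, taken from the median of its listed probe sets, is biased upward by the selection. Where 1 group lay under the 25th percentile of probe set means, 2.41 log2 units, the signal was near background and the fold is not exact: among the folds below this holds for DCLK1, PDK4, NDUFA2, HSD17B7, ZEB1, DLGAP5, EPHB2, DDIT3 and ABCA12. OBSL1, MPP4, CCDC146, ITGA1 and XRRA1 are given by their levels for the same reason. Genes with at least 5 listed probe sets included DCLK1, a microtubule-associated kinase (10.1-fold higher), the co-receptor NRP1 (7.74-fold higher), the apoptosis inhibitor BIRC3 (5.65-fold higher) and the adhesion protein CDH1 (4.18-fold lower). Of 335 genes with at least 2 listed probe sets, 5 had folds over 1.5 times apart when the median of the probe set changes replaced the change of the median per array, a summary added after the values were seen.

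**Figure D1:**
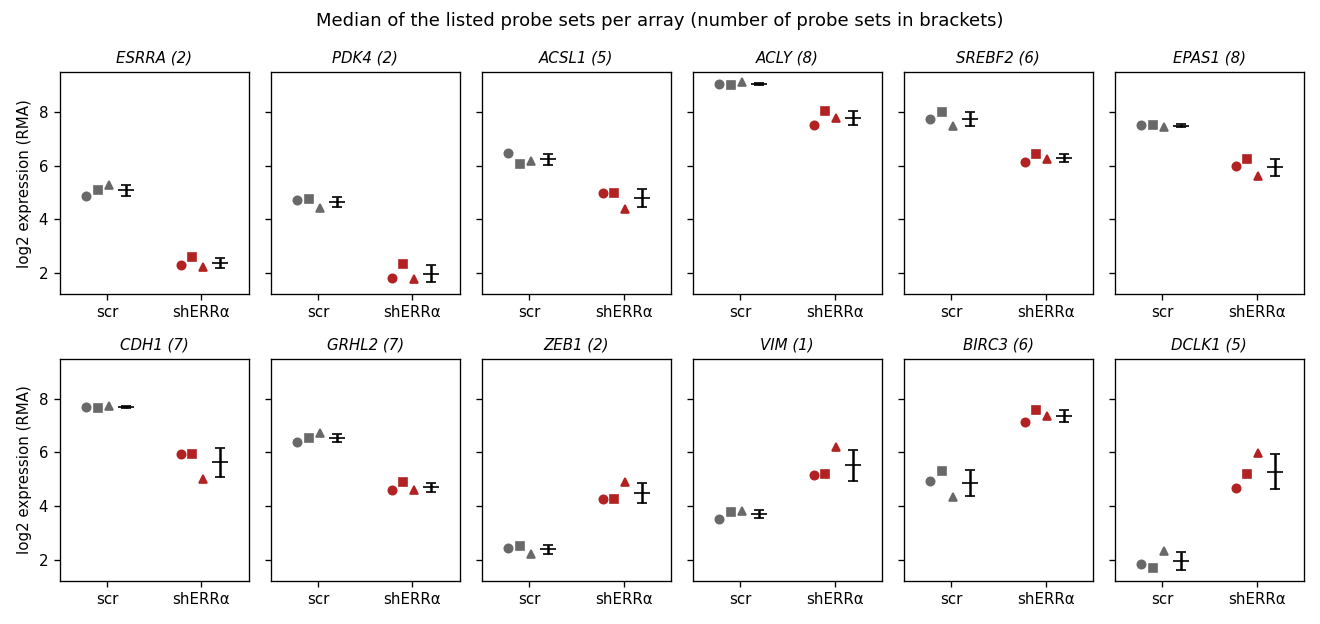
Log2 expression (vertical axis) of 12 genes on each of the 3 shscrambled (grey) and 3 shERRα (red) arrays, as the median of the gene's listed probe sets; circles, squares and triangles are replicates 1, 2 and 3, and the bars give mean ± SD. For ESRRA the shscrambled arrays lie at 4.86 to 5.28 and the shERRα arrays at 2.23 to 2.60.

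Of all genes listed in 1 direction 65.0% were lower, the share against which the directions in the gene lists below are read. The share of all measured genes that was listed is not known, because only listed probe sets carry names. As a rough guide, 1429 listed genes had a run among the 19182 tested runs. Counts of listed members were not tested against such a share. Of 39 textbook ERRα targets, 5 were listed, all lower: ESRRA, PDK4, ACSL1, SDHD and PDHA1. PDK4, the kinase that inhibits pyruvate dehydrogenase, was 6.34-fold lower (4.64 ± 0.18 against 1.97 ± 0.31, SD, n = 3), and ACSL1, which activates long-chain fatty acids, was 2.71-fold lower over 5 probe sets. Of 27 fatty acid oxidation genes, 4 were listed lower, among them ACSL1, ACAA2 and CPT1A, the carnitine palmitoyltransferase of the outer mitochondrial membrane (2.61-fold lower over 4 probe sets). The tricarboxylic acid cycle and pyruvate dehydrogenase list had 4 of 31 members listed lower, SDHD, PDHA1, PDK4 and PDK3. PDK3 and PDK4 inhibit pyruvate dehydrogenase, whereas PDHA1 is a subunit of it. SDHD, PDHA1 and ACAA2 were each listed by 1 probe set; the runs holding PDHA1 and ACAA2 had median log2 changes of -0.13 and -0.08, and SDHD had no run value. Among 17 ERR receptors and coregulators, 3 were listed, all lower, including ESRRA and the coactivator PPARGC1B (2.32-fold lower at 1 probe set, with a run median of -0.37).

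Of 37 complex I genes, 2 were listed lower at 1 probe set each, NDUFA2 (3.27-fold, run median -0.46) and NDUFV1 (2.18-fold, run median -0.90). Of 41 genes of complexes II to V, SDHD was listed lower and ATP5MG higher. The mitochondrial ribosome had 1 of 66 members listed, MRPL44, and the mitochondrial biogenesis list 2 of 30, the transcription elongation factor TEFM and the import receptor TOMM20, all lower. For ATP5MG, MRPL44 and TEFM the listing rested on a single probe set, and the runs holding them had median log2 changes of -0.36, -0.12 and 0.15. In the glutamine and serine list, the transaminases GOT1 (2.39-fold, 3 probe sets) and GPT2 (3.13-fold, 1 probe set, run median -0.61) were lower, 2 of 19 members.

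Of 23 cholesterol synthesis genes, 8 were listed lower and 1 higher. The lower ones included SREBF2, the main transcription factor of this pathway (2.73-fold over 6 probe sets), FDPS, FDFT1, CYP51A1, MSMO1, HSD17B7 and STARD4. HSD17B7 was 6.45-fold lower at a single probe set, with a run median of -0.37. Among 13 fatty acid synthesis genes, SREBF1 (2.88-fold), FADS1 (2.45-fold) and ATP citrate lyase ACLY (2.43-fold over 8 probe sets, 9.05 ± 0.05 against 7.77 ± 0.26, SD, n = 3) were listed lower and none higher. SREBF1 rested on 2 probe sets, with a run median of -0.45.

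Of 25 hypoxia and angiogenesis genes, 6 were listed, all lower. These were EPAS1, which encodes HIF-2α (2.94-fold over 8 probe sets), the collagen-modifying enzymes P4HA1 (2.99-fold over 7 probe sets), P4HA2 and PLOD2, and ANKRD37 and ERO1A. In the epithelial and mesenchymal adhesion list, 6 of 35 members were listed lower and 2 higher. CDH1, which encodes E-cadherin, was 4.18-fold lower over 7 probe sets (7.69 ± 0.03 against 5.63 ± 0.55, SD, n = 3), and CLDN7, OCLN, LAMA3, FN1 and MMP14 were listed lower, MMP14 at 1 probe set with a run median of -0.02. ZEB1, a repressor of CDH1, was 4.27-fold higher over 2 probe sets, and vimentin, VIM, 3.51-fold higher at 1 probe set (chosen after its values were seen). Of 27 intestinal differentiation genes, DPP4 (10.1-fold over 3 probe sets) and CA2 were listed lower, and MUC2 and SLC26A3 higher, SLC26A3 at 1 probe set with a run median of 0.14.

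The replication genes RFC2 (3.03-fold) and CDC25A (3.11-fold) were listed higher, 2 of 43, as were the mitotic genes DLGAP5 (4.43-fold) and UBE2C (2.05-fold), 2 of 43, each by 1 probe set. RFC2 and UBE2C had run medians of 0.38 and 0.29. The pocket proteins RBL2 (6.11-fold) and RB1 (2.07-fold) were listed lower, 2 of the 12 cyclin-dependent kinase inhibitors and RB family genes. RBL2 rested on 2 probe sets and RB1 on 1, with run medians of -0.74 and -0.80. FBXW7 was the only one of 30 p53 targets listed (2.48-fold higher), and BIRC3 the only one of 31 apoptosis regulators (5.65-fold higher, 6 probe sets, 4.86 ± 0.50 against 7.36 ± 0.22, SD, n = 3). In the Wnt and MYC target list, 3 of 24 were listed: AXIN2 higher, and CD44 and EPHB2 lower. EPHB2 was 4.91-fold lower at 1 probe set with a run median of -0.02.

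In the interferon list, HERC5 (2.81-fold over 3 probe sets), IFIH1, STAT2 and IFI6 were listed lower, 4 of 34. The lysosome and autophagy list had 4 of 30 listed lower, GAA, LAMP2, ULK1 and ATG5, of which ULK1 and ATG5 rested on 1 probe set each with run medians of -0.02 and -0.08. The stress response list had 1 of 27 listed, DDIT3 (2.93-fold lower). No member was listed of glycolysis, antioxidant defence, heat shock proteins, the cytosolic ribosome, replication-dependent histones or the neural and HEK293-type markers. Of markers of other cell types, 1 of 15 leukocyte markers was listed, ITGAM (higher), and 4 of 16 fibroblast and endothelial markers, COL3A1 and KDR higher and COL1A2 and COL6A3 lower. Each of these 5 rested on 1 probe set, and their runs had median log2 changes between -0.11 and 0.43.

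A listed direction that goes with a gene list was tested for the 3 lists with at least 5 listed members, against the other listed genes. ESRRA was left out, since the shRNA targets it, which leaves 4 listed ERRα targets and no test for them. Fisher's exact test gave two-sided p = 0.0970 for hypoxia (6 lower, 0 higher), p = 0.173 for cholesterol synthesis (8 lower, 1 higher) and p = 0.721 for adhesion (6 lower, 2 higher). Benjamini-Hochberg adjusted values were 0.260 for hypoxia and cholesterol synthesis, and 0.721 for adhesion. None of these lists passed. Most listed genes were lower, so even 6 of 6 members lower gave only p = 0.0970 by Fisher's exact test. A list with 6 listed members could therefore not pass as lower, and the missing pass for hypoxia says little.

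The 5 genes with the smallest limma p in each direction were mostly listed by 1 probe set. OBSL1 (0.60 against 4.27 log2 units), MPP4 (1.05 against 4.60), CCDC146 (1.78 against 5.33) and MTSS2 were listed higher by 1 probe set each, and NRP1 (4.81 ± 0.61 against 7.76 ± 0.42, SD, n = 3) by 5. Their runs had median log2 changes of 0.04 for OBSL1, 0.95 for MPP4, -0.36 for CCDC146, 0.10 for MTSS2 and 2.57 (SE 0.39) for NRP1. On the lower side were ESRRA, the integrin ITGA1 (4.76 against 1.05 log2 units, 1 probe set, run -1.17), XRRA1 (4.93 against 1.41 log2 units, 1 probe set, run -0.45), the lipid transporter ABCA12 (4.25-fold, 3 probe sets, run -1.30) and ATP6V1C2, whose probe sets were listed in both directions (run -1.20). None of these 10 genes passed the adjusted threshold.

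Genes with at least 5 listed probe sets were chosen after their values were seen: 12 were listed higher, 29 lower and COL4A6 both ways. Among the higher ones, MACF1 had 13 listed probe sets in a run of 99 (2.15-fold). DICER1, the ribonuclease that processes microRNA precursors, had 12 in a run of 30 (2.36-fold) and the Notch ligand JAG1 9 in a run of 30 (2.32-fold). DCLK1 (1.95 ± 0.34 against 5.28 ± 0.66, SD, n = 3), SH3RF2 (3.54-fold), the kinase SGK1 (3.45-fold), NAV3 (3.14-fold), the ectonucleotidase NT5E (2.77-fold), TNS4 (2.52-fold), ANKRD52 (2.48-fold), NRP1 and BIRC3 complete that group. Among the lower ones, NOTCH2 had 11 listed probe sets (2.58-fold), CDH3 8 (2.09-fold), MPP7 8 (2.69-fold), TMEM87B 8 (2.57-fold) and GRHL2, a transcription factor of epithelial cells, 7 (3.59-fold). For 2 genes the fold depended on the summary: CTH, an enzyme of cysteine synthesis with 7 listed probe sets, was 3.02-fold lower by its median per array and 5.52-fold by its probe set changes (run -2.30), and the receptor tyrosine kinase AXL 5.40-fold and 3.36-fold (run -0.96). CR2 (4.36-fold), SLC44A1 (3.15-fold), the splicing regulator ESRP1 (2.82-fold), FGFR2 (2.32-fold), HDAC3 (2.23-fold), BMPR1A (2.21-fold) and ITGAV (2.21-fold) were also lower. CKMT1A was 2.68-fold lower, a value that cannot be assigned to it alone because a nearly identical copy, CKMT1B, exists.

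For all 39 of these genes that were listed in 1 direction and had other probe sets in the same run, the median of those other probe sets lay in the listed direction, and the median of these values was 1.12 log2 units. Single probe sets could differ: for DCLK1, listed higher, 5 of the 13 others were lower, and for FGFR2, listed lower, 5 of the 21 others were higher. For genes with 1 listed probe set the median of the others lay in the listed direction for 878 of 1115, with a median of 0.25.

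**Figure D2:**
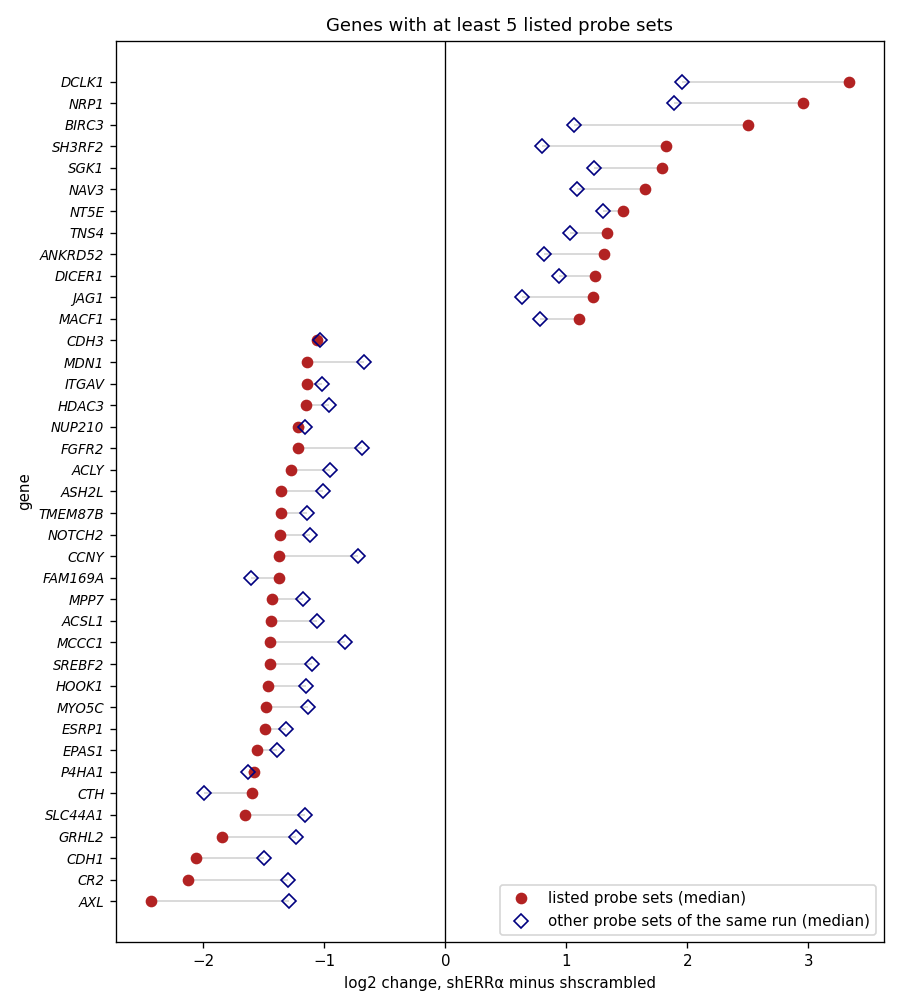
Log2 change between shERRα and shscrambled (horizontal axis) for the 39 genes with at least 5 listed probe sets in 1 direction and other probe sets in the same run; red circles are medians of the listed probe sets and open diamonds medians of the other probe sets of the run. For DCLK1 the values are 3.33 and 1.95, and for CDH1 -2.06 and -1.50.

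No probe set passed an adjusted p of 0.05 in limma (0 higher and 0 lower of 256161), while 6962 higher and 11577 lower, 18539 in all, had an unadjusted p under 0.05, against 8609 to 14196 for other splits of the arrays. For runs of at least 3 consecutive probe sets, a stand-in for genes added after the values were seen, the median per run gave 0 higher and 0 lower of 19182, with 630 higher and 1409 lower, 2039 in all, at an unadjusted p under 0.05, against 390 to 1272 for other splits. With array weights, which gave shERRα replicate 1 a weight of 0.323, 24 runs passed as higher and 54 as lower; with the mean in place of the median, 25 passed as higher and 132 as lower. In simulated data with 200 changed probe sets or runs and independent noise, no probe set changed by 1 or 2 log2 units was called (0 of 100 each). Run medians called 19.0% and 89.0% of such changes. At that setting the absence of calls for probe sets says little about change, but the real number of changes is not known. Run medians were less blind in the simulation, yet the real runs of DCLK1 and NRP1, at 2.62 and 2.57 log2 units, were not called.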

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

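The units tested (probe sets and runs), the deposited rule as a result of its own, runs of other lengths, the inclusion of undecided probe sets and the median of probe set changes as a gene's summary were chosen after the data were seen; the remaining settings applied to them were planned. The ESRRA probe sets stayed lower in every setting run, and the 781 values of the other 71 named genes kept their direction, which says little about stability because these genes were listed for their difference on the same arrays and the block leaves a log2 change as it is.

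At an adjusted p under 0.05 limma called 0 probe sets in every setting run, and so did an equal-variance test, which at an unadjusted p under 0.05 gave 7480 higher and 11084 lower. The rule of p under 0.01 and 2-fold gave 695 higher and 1427 lower. With a replicate block it gave 392 and 675, and above the median level 270 and 854. Leaving out each array in turn gave 513 to 906 higher and 775 to 1705 lower; without shscrambled replicate 2 it gave 775 lower, and without shscrambled replicate 1 909.

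Runs went from 0 higher and 0 lower by their median to 25 and 132 by their mean, 0 and 2 by their brighter probe sets, and 24 and 54 with array weights. With weights, runs of any length gave 24 and 40, and runs of at least 5 gave 38 and 126. Without each array in turn there were 0 to 1 higher and 0 to 2 lower; with a replicate block there were 0 and 0. Several combinations of summary, length and weights were tried, so the calls of any single one are open to that choice. The cause of these differences was not tested.

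Arrays of the same replicate number had correlations of deviations of 0.068, 0.048 and 0.084, and every array correlated best with its own number. Pairs of different numbers had -0.0602 to -0.00452. The values were small and the main fit did not pair the arrays, but a weak pairing stays open. At limma's unadjusted p under 0.05, the replicate block gave 764 runs higher and 1615 lower, against 630 and 1409 without it. The gene-level fit, camera with a preset and an estimated correlation and on ranks, fry, and the gene-level overlap with the deposited comparison were not run. With at least 2 listed probe sets per gene, no list had enough members for its test. Signal near background limits what dim probe sets can show: the 25th percentile of probe set means was 2.41 log2 units.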

Other observations

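The tests on the excess of lower probe sets, cells of another type and the counts over other splits of the arrays, except that of runs with at least 5 probe sets, were chosen after the results were seen.

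Of the listed genes, 46 lay in runs that passed limma's adjusted threshold both with array weights and with the run mean. Several are in none of the lists, and the following were chosen after their values were seen. ARRDC4, an arrestin-domain gene, had a run change of -2.36 log2 units, the secreted protease inhibitor SLPI -1.77, the orphan receptor NR2F1 -1.89, MAL2, a transport protein of polarised epithelia, -1.57, and the TGF-β pathway repressor SKIL -1.77. On the other side, the DNA repair factor XRCC4 had 1.93, the carboxypeptidase CPA4 1.55, and CYP39A1, an oxysterol hydroxylase, 1.58. Without weights and with the median, none of these passed.

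More listed probe sets were lower (67.2%) than higher. Without shERRα replicate 1 the share was 65.5% (exact 95% binomial interval 63.2 to 67.6, which treats probe sets as independent), which argues against the scale of that array as the source. The share was 76.0% above the median level and 57.4% below it, a difference of 18.6 percentage points. This split cannot decide on signal near background, because a probe set near background can rise 2-fold but hardly fall 2-fold. Listed lower probe sets had a median level of 4.94 log2 units and listed higher ones 3.50. After quantile normalisation it was 59.7% (57.5 to 61.8), between the bounds set for this test, so part of the excess may come from the normalisation between arrays. Depletion of a transcriptional activator is an explanation that the design offers, and it was not tested separately. With a single shERRα group and a scrambled control, it cannot be told apart from other effects of the shRNA.

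shERRα replicate 1 stood apart from the other 5 arrays. Its deviation from the other shERRα arrays correlated with their response across runs at 0.016 and -0.023, so no sign of a stronger response of the same kind was seen. The test could hardly show a moderately stronger one, because even the full difference from shscrambled arrays correlated weakly, as given below. In the probe sets at or above the 75th percentile of levels its differences from replicates 2 and 3 had a mean SD 1.96 times that of the differences between those replicates, so noise in dim probe sets alone does not account for it. Correlations cannot decide whether it is a shscrambled sample under its label. Its difference from shscrambled arrays correlated with the response of replicates 2 and 3 at 0.102 to 0.218. Differences between shscrambled arrays reached 0.204 in size. ESRRA, however, was at 2.29 log2 units in replicate 1, within the 2.23 to 2.60 of the other shERRα arrays. The shscrambled arrays lay at 4.86 to 5.28, so the target gene argues against a shscrambled sample under this label. Its named probe sets were, however, selected on these same arrays, replicate 1 included. RNA quality or hybridisation stays open and was not tested.

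CDH1, GRHL2 and ESRP1 were lower while ZEB1 and VIM were higher, which may be a shift from epithelial towards mesenchymal expression. However, FN1 (2.26-fold), MMP14 (3.48-fold), AXL (5.40-fold, or 3.36-fold by its probe set changes) and CD44 (2.46-fold), genes often linked to mesenchymal cells, were listed lower. FN1, MMP14 and CD44 each rested on 1 probe set, with run medians of -0.99, -0.02 and -0.93, so MMP14 says little here. VIM also rested on 1 probe set, with a run median of 1.79. Without each shERRα array in turn, the smallest fold among CDH1, GRHL2, ESRP1, ZEB1 and VIM was 2.55. Genes listed for separated groups could hardly lose their difference this way, so the weight of a single array stays open. The other probe sets of their runs had a median of at least 0.5 log2 units in the same direction for 5 of 5 genes. For CDH1, GRHL2 and ESRP1, with at least 5 listed probe sets each, this was nearly given. For all 39 such genes the others lay in the listed direction. For ZEB1 (0.53) and VIM (0.89) the values argue against a chance extreme of a single probe set. They do not argue against a choice of genes on these same arrays. Cells of another type stay open: of the 1 fibroblast and endothelial marker listed above the 25th percentile of levels, 0 were lower. The shift remains a hypothesis, since GRHL2, ESRP1 and VIM were picked after their values were seen. The adhesion list mixes epithelial and mesenchymal genes, so its Fisher's exact p = 0.721, a test for 1 shared direction, cannot decide on such a shift.

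The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. The rule of the deposited comparison gave 2122 probe sets for the real split and at most 1173 for any other, so 1 split reached the real count. Runs with at least 5 probe sets past the rule in 1 direction numbered 41, against at most 6. Run means gave 157 calls against 0, and run medians with array weights 78 against 51. That 51 came from the split that joined shERRα replicate 1 to shscrambled replicates 1 and 2, and the same split gave 0 calls by unweighted medians and 0 by means. For unweighted limma on probe sets and on run medians, all 10 splits gave 0.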
